A study of Mus musculus with 8 samples.

How the data were processed

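RNA levels were measured in 3T3-L1 adipocytes, fat cells grown from a mouse fibroblast line, with and without tunicamycin, an inhibitor of the first step of N-linked protein glycosylation. Total RNA was extracted with Trizol, biotin-labelled and hybridised to Affymetrix arrays, per the labels. There were 8 arrays in 6 groups. The labels give 1 control and 1 tunicamycin array at 4 h, 2 control arrays and 1 tunicamycin array at 8 h, and 1 control and 2 tunicamycin arrays at 12 h. The labels call the replicates biological, so the p-values at single times rest on the spread between cultures as labelled. In the model over all times, the residual also holds any difference of the effect between times. Its standard errors and p-values are therefore not a measure of the spread between cultures alone. The tunicamycin dose is not given in the sources used here.

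The deposited table of each array holds 1 linear intensity per probe set, per the file headers, and the software and scaling behind these values are not given in the sources used here. Values at or below 0 made up 19.2% to 20.9% of each array. The median deposited intensity of the 8 arrays ran from 9.56 to 22 and the mean from 114 to 257. The gap between array medians was 0.997 on the log2 scale. Under a rule fixed before the data were examined, a gap above 0.3 called for quantile normalization. The arrays were quantile normalized on the linear scale, and values below 0 were then set to 0. After that log2(value + 2.956) was used, where 2.956 is the 10th percentile of the positive deposited values. A fold change on this scale understates the change of genes with low values, and no fold is given for a named gene at or below 0 on an array of the comparison; nor is one where every array of a group lies below the pseudocount. Fitted differences between times that rest on such an array are marked as no folds, and intensities near the pseudocount are given beside the folds that rest on them. No 2 arrays held identical values (0 pairs). The columns matched to no sample numbered 0. The number of arrays limits the precision of every estimate.

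Separate tables of the authors hold a log10 ratio and a p-value per probe set for tunicamycin against control at each time, as deposited. The direction of these ratios is not stated. Ratios above 0 were read as higher with tunicamycin, because across genes they correlated positively with the effects computed here at each time. How the authors computed the ratios and p-values is not given in the sources used here, and those tables entered no test.

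Of the 45101 probe sets, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211 had none. The gene IDs of 34754 of the probe sets with 1 symbol were found in a RefSeq gene table of assembly GRCm38.p6, which was used for current names only, and the others kept the annotation's symbol. Probe sets with several symbols or none entered no gene test. Each of 18194 genes was represented by its probe set with the highest mean log2 value over the 8 arrays. The 10916 genes with a mean log2 value at or above the 40th percentile, 4.19 or about 15.3 intensity units, were tested. No genome was used, so no coordinates are given.

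Tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and figures used matplotlib 3.10.9 in Python 3.11.15. The effect of tunicamycin over all times was the treatment coefficient of an additive model with time point and treatment, which has 4 residual degrees of freedom and 5.89 prior ones. The effects at 4 h, 8 h and 12 h, and their differences, were contrasts in a model with 1 mean per group, which has 2 residual degrees of freedom and 6.37 prior ones. Those 2 come from the 8 h controls and the 12 h tunicamycin arrays, so each lone array is assumed to vary like the replicated groups. Whether the effect differed between times was tested with limma's moderated F test on 2 contrasts, 8 h minus 4 h and 12 h minus 4 h. Genes were called at an adjusted p under 0.05 (Benjamini-Hochberg). All p-values are two-sided, and every adjusted p comes from limma or its camera test.

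Gene lists were written from general knowledge before the data were examined, as were the models, the filter, most alternatives and the rule for naming genes. They cover ER chaperones and folding enzymes, ER-associated degradation, unfolded protein response sensors and transcription factors, the ATF4 and CHOP stress response, amino acid synthesis and transport, cytosolic aminoacyl-tRNA synthetases, N-glycosylation, ER translocation and ER-Golgi transport, adipocyte markers, fatty acid synthesis, cholesterol synthesis, insulin signalling and glucose uptake, the inflammatory response, apoptosis, the cell cycle, the mitochondrial respiratory chain, ribosomal proteins, extracellular matrix and fibroblast markers, the oxidative stress response, cytosolic heat shock proteins, autophagy and lysosome, substrates of IRE1-dependent decay, glycolysis and hypoxia, the circadian clock, and markers of macrophages, endothelium and skeletal muscle. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with a correlation estimated from the data. Benjamini-Hochberg adjustment ran over the 25 tested lists within each comparison. Some genes stand in more than 1 list.

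The named genes are, over all times, the 10 highest and 10 lowest called log2 fold changes among genes whose every tunicamycin array lay on the same side of every control array of its time. At each single time they are the 5 highest and 5 lowest called. For effects that differ between times, they are the 5 called genes with the largest rise of the effect from 4 h to 12 h and the 5 with the largest fall. For the change over time common to both arms, they are up to 5 called in each direction. For each list they are up to 4 called members with the largest change over all times, or, where none was called, the 2 with the smallest p. The genes Hspa5, Ddit3, Xbp1, Dpagt1, Atf4, Herpud1, Slc2a4, Slc2a1, Insr, Irs1, Pparg, Cebpa, Adipoq, Lep and Fabp4 were always included. Of 99 named genes looked up for further probe sets, 56 had other tested ones; 6 had at least 1 of opposite direction (Ern1, Slc7a1, Mcm3, Mcoln1, Ctsa and Pfkp), and 0 had one called in the opposite direction.

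The alternatives set other scalings, pseudocounts, filters, probe set rules and variance settings, a replicate block, and each array left out in turn. The models were tested on simulated data of 10916 genes, with each gene's fitted spread and noise drawn independently for each gene. Of 100 genes changed 2-fold, the test over all times recovered 85% and the tests at 4 h, 8 h and 12 h recovered 57%, 65% and 63%. Of 100 changed 4-fold, the same tests recovered 98%, 90%, 87% and 89%, with 11, 10, 17 and 11 false calls. Each of these simulated changes was the same at all times, so the 85% and 98% do not cover effects that differ between times. The F test recovered 179 of 200 genes changed 4-fold at 12 h alone, with 17 false calls. In a simulated list test, camera called the shifted list with either correlation and 0 of 24 unchanged lists. The simulated genes were not correlated, so this does not test how correlation within a real list (estimated at up to 0.724 over all times) affects its calls.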

Results

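Gene expression was measured in 3T3-L1 adipocytes, a mouse cell line that is differentiated into fat cells in culture, under control conditions or after exposure to tunicamycin. Tunicamycin blocks the first step of N-linked glycosylation, and glycoproteins then fold poorly in the endoplasmic reticulum (ER), which sets off the unfolded protein response. Of the 8 arrays, 4 were controls (1 at 4 h, 2 at 8 h and 1 at 12 h) and 4 were tunicamycin arrays (1 at 4 h, 1 at 8 h and 2 at 12 h). Each array measured 45101 probe sets. Values below are normalized intensities and log2 fold changes of tunicamycin over control, with the standard error (SE) of the limma fit. Over the tested genes, the 2 control arrays at 8 h correlated at r = 0.984 and the 2 tunicamycin arrays at 12 h at r = 0.973. The 4 h tunicamycin array correlated at r = 0.973 with the 4 h control. The 8 h and 12 h tunicamycin arrays correlated with the controls at r = 0.922 to 0.948, and with one another at 0.963 or above. The 4 h tunicamycin array stood apart in its RNA quality probes. Its ratio of 3' to 5' signal was 2.81 for beta-actin, against 1.51 to 1.82 in the controls, and 43.5 for pyruvate carboxylase, against 12.1 to 15.3. A second difference followed time: the ratio of the hybridisation controls BioC and BioB was 2.55 to 2.82 on the 4 h and 8 h arrays and 0.905 to 0.995 on the 12 h arrays, while that of BioD and BioB overlapped (6.95 to 8 and 7.25 to 9.71). The labels name no batch.

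The first comparison asked which transcripts differed with tunicamycin over all times. The genes with the highest fold changes included ER chaperones, factors that clear misfolded protein from the ER, and the transcription factors and targets of the stress response. Creld2, an ER chaperone-like protein, rose from a mean of 223 ± 10 in controls to 4960 ± 2270 with tunicamycin (SD, n = 4 arrays each over the 3 times), a log2 fold change of 4.20 (SE 0.265, adjusted p = 3.17e-05). Sdf2l1, a chaperone partner, rose by 4.16 (SE 0.425, adjusted p = 0.000502), and Herpud1, an ER membrane protein of the degradation machinery, by 3.62 (SE 0.102, adjusted p = 5.12e-08). Ddit3, which encodes the transcription factor CHOP, went from 694 ± 132 to 6330 ± 1050 (SD, n = 4 arrays each), a log2 fold change of 3.18 (SE 0.0821, adjusted p = 4.25e-08). Ppp1r15a, which encodes the phosphatase subunit GADD34, rose by 3.38, the pseudokinase gene Trib3 by 3.30 and Chac1, which encodes a glutathione-degrading enzyme, by 2.98. The branched-chain aminotransferase gene Bcat1 rose by 3.08 (SE 0.466), Mreg by 3.08 (SE 0.629; an intensity of 3.75 on the 12 h control) and Tes, which encodes a focal adhesion protein, by 2.87 (SE 0.482; 3.25 on control 8 h replicate 1).

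The genes named as lower over all times were chosen among those with every tunicamycin array below the controls of its time. Crip1, which encodes a LIM domain protein, went from 92.6 ± 26.8 to 13.2 ± 10.6 (SD, n = 4 arrays each, adjusted p = 0.0118), and was at or below 0 on 1 tunicamycin array. Dusp4, a phosphatase acting on MAP kinases, fell by 2.46 (SE 0.419, adjusted p = 0.00451). Ankef1 fell by 2.30 (2.01 on tunicamycin 12 h replicate 1), the growth factor gene Gdf5 by 2.24, the scavenger receptor gene Scara3 by 2.24 and Gas7 by 2.21. Kctd12b fell by 2.21, C1qtnf6 by 2.16 (4.66 on the 8 h tunicamycin array), Hcar1, the lactate receptor of fat cells, by 2.12, and Rgcc by 2.11. All genes named here as lower lost their calls when no filter was used, with adjusted p from 0.0518 (Gdf5) to 0.171 (Ankef1). Without the 8 h tunicamycin array, the calls of Tes (adjusted p = 0.0646), Dusp4 (0.0668), Kctd12b (0.0593), Hcar1 (0.0504) and Rgcc (0.0676) were lost. The calls of Mreg, Crip1 and C1qtnf6 were lost without that array or without the 12 h control, with adjusted p up to 0.089, 0.0973 and 0.116; Mreg was at 1.96 without the 12 h control. Ankef1 lost its call without either of these or without control 8 h replicate 2 (adjusted p up to 0.151), and was at -1.34 without the 12 h control. With the mean of all probe sets Ankef1 was at -0.824 (adjusted p = 0.0614) and Gas7 at -0.95 (0.0667), both uncalled.

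In all, 2264 of the 10916 tested genes (20.7%) were called, 1207 higher and 1057 lower, and 275 and 213 of them were at least 2-fold changed. Of all tested genes, called or not, 4248 (38.9%) had every tunicamycin array on the same side of its time's controls, which chance gives in 11.1%; 2123 of these were called. Within the arrays on each side of the BioC to BioB difference, the 4 h and 8 h arrays alone gave 347 higher and 140 lower genes, and the 12 h arrays alone 956 and 936. Single arrays moved these counts. Genes higher numbered 736 without control 8 h replicate 2, 270 without the 8 h tunicamycin array and 607 without the 12 h control. Genes lower numbered 639 and 546 without control 8 h replicates 1 and 2, 104 without the 8 h tunicamycin array, 334 without the 12 h control, and 687 and 697 without tunicamycin 12 h replicates 1 and 2. With the deposited scaling kept, 143 genes were higher and 707 lower, 16.8% higher against 53.3% after quantile normalization, and the median of all genes shifted to -0.31. Median centring gave 794 higher, the mean of all probe sets of a gene 702 higher, no filter 400 higher and 178 lower, and variances without an intensity trend 600 lower. Of 156 values of named genes in this text, over all times or otherwise, 98 lost their calls without a filter, 50 with the deposited scaling and 47 without an intensity trend. Cebpa (adjusted p = 0.102) and Irs1 (0.0954) lost theirs over all times without a filter, Pparg without a filter (0.185) or the trend (0.0803), and Xbp1 with the deposited scaling (0.566; a log2 fold change of 0.286); Creld2, Herpud1, Ddit3, Atf4 and Hspa5 kept theirs in these 3 settings (adjusted p up to 0.025).

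**Figure D1:**
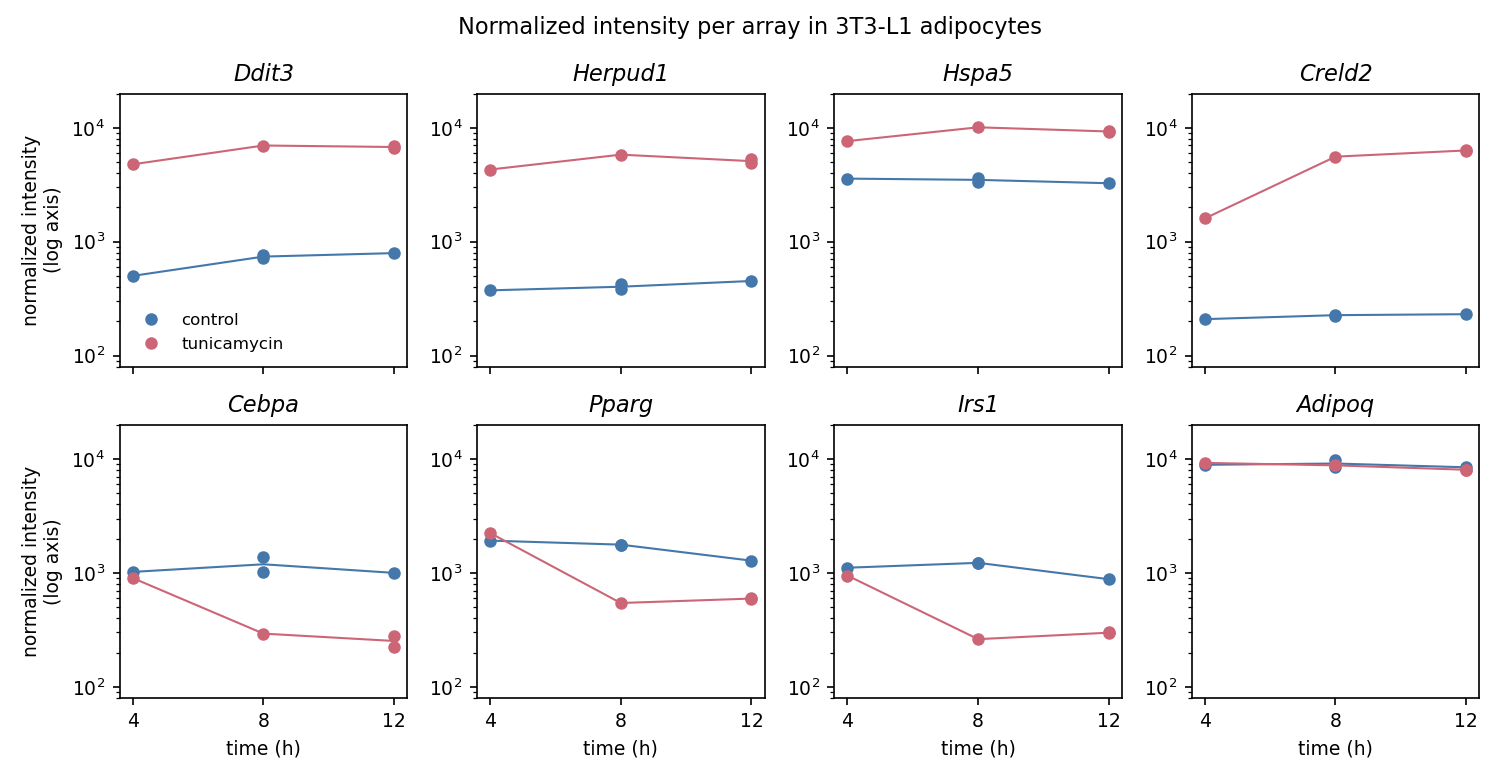
Normalized intensity (log axis) of 8 genes against time in hours, with 1 point per array and a line through the group means of control and tunicamycin arrays. Tunicamycin arrays lie above the controls at each time for Ddit3, Herpud1, Hspa5 and Creld2; for Cebpa, Pparg and Irs1 the arrays of the 2 groups lie apart at 8 h and 12 h, and for Adipoq the tunicamycin mean of 8530 lies within 1 control SD (601) of the control mean of 8900.

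Genes for protein folding in the ER rose together. Of 28 tested ER chaperones and folding enzymes, 23 were higher and 0 lower (24 and 0 adjusted over the list alone), with a median log2 fold change of 1.32. Besides Creld2 and Sdf2l1, Dnajc3, an inhibitor of the eIF2alpha kinase PERK, rose by 2.56 (SE 0.208, adjusted p = 0.000152) and Ero1a, the ER oxidase, by 2.45 (SE 0.278). Hspa5, which encodes the major ER chaperone BiP, rose from 3450 ± 189 to 9070 ± 1020 (SD, n = 4 arrays each), a log2 fold change of 1.40 (SE 0.0911, adjusted p = 3.74e-05). The list differed from other genes by camera with an adjusted p = 5.38e-17, and with adjusted p = 0.311 with an estimated correlation. In all, 13 of the 25 tested lists were called over all times, 8 higher and 5 lower, and 0 with an estimated correlation. That form of the test has few degrees of freedom, so its 0 does not show that correlation among genes makes up the calls. Of 23 genes of ER-associated degradation, 15 were higher and 0 lower (16 and 0 adjusted over the list alone), with a median of 0.628 (adjusted p = 4.28e-10, and adjusted p = 0.311 with an estimated correlation). Sel1l, an adaptor of the degradation complex, rose by 2.65, Edem1, which recognises misfolded glycoproteins, by 2.22 and Syvn1, the ubiquitin ligase HRD1, by 2.19.

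Of 19 unfolded protein response sensors and transcription factors, 11 were higher and 1 lower (13 and 1 adjusted over the list alone), with a median of 0.518 (adjusted p = 2.25e-06, and adjusted p = 0.282 with an estimated correlation). Atf4 rose by 1.49 (SE 0.0921, adjusted p = 3.08e-05), Atf6 by 1.46 (SE 0.186), and Ern1, which encodes the sensor IRE1, by 1.31 (SE 0.162). Of the 3 other tested probe sets of Ern1, 2 pointed the other way, uncalled. With the mean of all its probe sets Ern1 was at 0.206 and was not called (limma, adjusted p = 0.626). Xbp1, whose RNA IRE1 splices, rose by 0.64 (SE 0.0814, adjusted p = 0.00131). Splicing was not analysed here. In the list of ATF4 and CHOP stress response genes, 16 of 21 were higher and 0 lower (19 and 0 adjusted over the list alone), with a median of 1.04 (adjusted p = 5.72e-16, and adjusted p = 0.117 with an estimated correlation). Its named members are Ppp1r15a, Trib3, Ddit3 and Chac1, given above.

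Genes for amino acid supply rose as well. Of 22 amino acid synthesis and transport genes, 18 were higher and 0 lower (19 and 0 adjusted over the list alone), with a median of 0.93 (adjusted p = 1.49e-13, and adjusted p = 0.311 with an estimated correlation). Besides Bcat1, the cationic amino acid transporter Slc7a1 rose by 2.26 (SE 0.173), and Slc7a5 and Slc3a2, the light and heavy chains of a large neutral amino acid transporter, both by 1.89 (SE 0.213 and 0.117). Of 19 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 14 were higher and 0 lower, with the same counts adjusted over the list alone and a median of 0.772 (adjusted p = 2.11e-09, and adjusted p = 0.311 with an estimated correlation). The synthetases for tryptophan, isoleucine, leucine and asparagine, Wars, Iars, Lars and Nars, rose by 1.46, 1.24, 1.12 and 1.06.

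Genes of the pathway that tunicamycin blocks moved in both directions. Of 38 N-glycosylation genes, 13 were higher and 2 lower (15 and 3 adjusted over the list alone), with a median of 0.127 that turned to -0.179 with the deposited scaling, 0.132 above the median of all genes there. The list had an adjusted p = 0.00621, and an adjusted p = 0.525 with an estimated correlation. It was not called on the 4 h and 8 h arrays alone (adjusted p = 0.125) or without the 12 h control (0.0898), and was on the 12 h arrays alone (4.67e-06). Alg12, a mannosyltransferase, rose by 1.71 (SE 0.205), Rpn1, a subunit of the oligosaccharyltransferase, by 1.29 (SE 0.184), and Gnpnat1 and Gfpt1, enzymes of UDP-GlcNAc synthesis, by 1.28 and 1.26. Dpagt1, the enzyme that tunicamycin inhibits, had a log2 fold change of 0.91 (SE 0.249, adjusted p = 0.0305). Its call was lost without either 8 h control, the 8 h tunicamycin array, the 12 h control or tunicamycin 12 h replicate 2 (adjusted p up to 0.205), and its value was 0.547 without the 12 h control. Of 44 genes of ER translocation and ER-Golgi transport, 23 were higher and 0 lower (29 and 1 adjusted over the list alone), with a median of 0.45 (adjusted p = 1.55e-10, and adjusted p = 0.311 with an estimated correlation). Sec23b and Sec24d, coat proteins of vesicles leaving the ER, rose by 1.42 and 1.11, and Spcs2 and Spcs3, subunits of the signal peptidase, by 1.13 and 1.06. Without the 8 h tunicamycin array the calls of Gnpnat1 (adjusted p = 0.0651), Sec23b (0.0535), Spcs2 (0.0721), Sec24d (0.0724) and Spcs3 (0.0611) were lost.

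Markers of the differentiated adipocyte fell as a list. Of 24 tested, 0 were higher and 14 lower (1 and 17 adjusted over the list alone), with a median of -0.391 (adjusted p = 4.26e-06, and adjusted p = 0.311 with an estimated correlation). Cebpa, a transcription factor that maintains the fat cell, went from 1100 ± 181 to 425 ± 319 (SD, n = 4 arrays each), a log2 fold change of -1.5 (SE 0.288, adjusted p = 0.00721). Pparg, the master regulator of fat cell differentiation, fell by 0.96 (SE 0.258, adjusted p = 0.0284), Pck1, an enzyme of glyceroneogenesis, by 1.41 (SE 0.376) and Mgll, a lipase for monoacylglycerol, by 0.96 (SE 0.194). Adipoq, which encodes the secreted hormone adiponectin, had a log2 fold change of -0.03 (SE 0.0701, adjusted p = 0.803), with means of 8900 in controls and 8530 with tunicamycin. The value of Fabp4, -0.13 (SE 0.0779, adjusted p = 0.273), carries little information, because this gene held the highest value, 10800, on all 4 control arrays, where quantile normalization sets a common ceiling. Lep was below the filter and was not tested (mean log2 value 2.14). The calls of Cebpa and Mgll were lost without the 8 h tunicamycin array or the 12 h control (adjusted p up to 0.0904 and 0.0962). That of Pparg was lost without any 1 of the 6 arrays at 8 h and 12 h (adjusted p up to 0.233), and that of Pck1 without any of these except tunicamycin 12 h replicate 1 (up to 0.22). Pparg was at -0.535 without the 8 h tunicamycin array and Pck1 at -0.865 without the 12 h control. For Pparg the 4 h tunicamycin array lay above its control. The beta-actin 3' to 5' ratio of the 8 h and 12 h tunicamycin arrays was 1.67 to 1.71, above the 1.51 to 1.57 of the controls at those times. The ratios of GAPDH and pyruvate carboxylase were above the controls at 8 h (0.971 against 0.857 and 0.873, and 19.8 against 12.1 and 15.3) and below the control at 12 h (0.902 and 0.817 against 0.909, and 12.6 and 6.74 against 13.9).

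Of 19 fatty acid synthesis genes, 0 were higher and 7 lower, also when adjusted over the list alone, with a median of -0.293 (adjusted p = 0.00286, and adjusted p = 0.311 with an estimated correlation). Pnpla3, a lipid-remodelling enzyme, fell by 2.38 (SE 0.519) and Fasn, the fatty acid synthase, by 1.01 (SE 0.224), although at 4 h the tunicamycin array did not lie below the control for either. Acss2, which makes acetyl-CoA from acetate, fell by 0.70 and the desaturase Fads2 by 0.55. With the mean of all probe sets Acss2 was at -0.145 and was not called (limma, adjusted p = 0.668). Of 20 cholesterol synthesis genes, 3 were higher and 7 lower (3 and 10 adjusted over the list alone), with a median of -0.378 (adjusted p = 0.0203, and adjusted p = 0.311 with an estimated correlation). Dhcr7, the last enzyme of one branch of the pathway, fell by 1.54, Nsdhl by 0.88 and Srebf2, the transcription factor that drives the pathway, by 0.86, whereas the isomerase Ebp rose by 0.88. The cholesterol list was not called on the 4 h and 8 h arrays alone (adjusted p = 0.092) or without the 12 h control (0.0864), and was on the 12 h arrays alone (0.0115). Calls lost without the 8 h tunicamycin array were those of Dhcr7 (adjusted p = 0.067) and Srebf2 (0.0607). Those of Pnpla3, Fasn, Acss2, Fads2 and Ebp were lost without that array or without the 12 h control (adjusted p up to 0.125, 0.123, 0.0724, 0.0913 and 0.0831); Ebp was at 0.468 without the 12 h control.

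The insulin signalling and glucose uptake list was not called (adjusted p = 0.728), with 3 of 26 genes higher and 6 lower (3 and 8 adjusted over the list alone) and a median of -0.0208 that turned to 0.0233 when each array was divided by its mean. Within it Irs1, the adaptor that passes on the insulin receptor's signal, went from 1110 ± 164 to 452 ± 331 (SD, n = 4 arrays each), a log2 fold change of -1.43 (SE 0.268, adjusted p = 0.00642). Pik3r1, the regulatory subunit of PI3 kinase, fell by 0.80 (SE 0.127) and Tbc1d4, which controls glucose transporter traffic, by 0.60 (SE 0.18), although not on the 4 h array, while the kinase gene Gsk3b rose by 0.58 (SE 0.128). The insulin-responsive glucose transporter Slc2a4 had a log2 fold change of -0.34 (SE 0.124, adjusted p = 0.077). Slc2a1, the basal glucose transporter, had -0.02 (SE 0.102, adjusted p = 0.893), which became 0.0249 when each array was divided by its mean. The insulin receptor gene Insr had 0.09 (SE 0.145, adjusted p = 0.712), which became -0.204 with the deposited scaling. The calls of Irs1 (adjusted p = 0.0693) and Pik3r1 (0.0501) were lost without the 8 h tunicamycin array, that of Gsk3b without it or the 12 h control (up to 0.0952), and that of Tbc1d4 without any 1 of the 6 arrays at 8 h and 12 h (up to 0.263).

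Proliferation and matrix genes were lower as lists. Of 26 cell cycle genes, 0 were higher and 9 lower (0 and 10 adjusted over the list alone), with a median of -0.278 (adjusted p = 0.00355, and adjusted p = 0.525 with an estimated correlation). Birc5 and Ccnd1, which act in cell division and in entry to the cycle, fell by 0.84 and 0.78, and the replication helicase genes Mcm6 and Mcm3 by 0.84 and 0.75, although not on the 4 h array. Of 30 extracellular matrix and fibroblast markers, 2 were higher and 9 lower (2 and 10 adjusted over the list alone), with a median of -0.137 (adjusted p = 0.00497, and adjusted p = 0.525 with an estimated correlation). S100a4, a fibroblast marker, fell by 1.54 (SE 0.23), Lum, a matrix proteoglycan, by 1.47 (SE 0.174), the protease Mmp3 by 1.22 (SE 0.335) and the receptor Pdgfra by 1.21 (SE 0.222). On the 4 h and 8 h arrays alone the cell cycle list had an adjusted p = 0.117 and the matrix list 0.195, without the 12 h control 0.0864 and 0.155, and on the 12 h arrays alone 1.12e-05 and 1.14e-06. The calls of Birc5, Ccnd1 and Pdgfra were lost without the 8 h tunicamycin array or the 12 h control (adjusted p up to 0.0859, 0.0747 and 0.0791), and those of Mcm6 and Mcm3 without any 1 of the 6 arrays at 8 h and 12 h (up to 0.293 and 0.213). That of Mmp3 was lost without control 8 h replicate 2, the 8 h tunicamycin array, the 12 h control or tunicamycin 12 h replicate 2 (up to 0.221). Without the 12 h control Mcm6 was at -0.368, Mcm3 at -0.432, Ccnd1 at -0.492 and Mmp3 at -0.628.

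Lists not called over all times held single genes that were. Of 20 inflammatory response genes, 6 were higher and 1 lower (8 and 2 adjusted over the list alone; adjusted p = 0.0684). The cytokine gene Il6 rose by 2.83 (SE 0.336, adjusted p = 0.00102), the chemokine genes Cxcl5 and Cxcl1 by 1.42 and 1.17, and Nfkb2 by 1.16. This list was called higher without control 8 h replicate 1 (adjusted p = 0.0387) or without the 8 h tunicamycin array (0.0115), on the 12 h arrays alone (0.0467), with the deposited scaling (0.0133), without a filter (0.0191) and with every probe set tested (0.0014). Of 22 apoptosis genes, 4 were higher and 2 lower (4 and 3 adjusted over the list alone; adjusted p = 0.926). Traf2, an adaptor that IRE1 recruits, rose by 1.05 and the death receptor gene Fas by 0.87, while Bcl2l11, which encodes the pro-apoptotic protein BIM, fell by 1.20 and Casp12 by 0.98. Of 15 circadian clock genes, 6 were higher and 0 lower (6 and 3 adjusted over the list alone; adjusted p = 0.0905). The clock list was called higher with the deposited scaling (adjusted p = 0.0298) and without a filter (0.0287). Per1 rose by 1.33, Nfil3 by 1.32, Ciart by 1.31 and Cry1 by 1.16. The medians of these 3 lists, 0.0849, 0.0396 and 0.27, turned to -0.224, -0.237 and -0.0401 with the deposited scaling, and lay 0.086, 0.0733 and 0.27 above the median of all genes there. Without the 8 h tunicamycin array the calls of Nfkb2 (adjusted p = 0.0643), Casp12 (0.0681) and Cry1 (0.0863) were lost, and without it or the 12 h control that of Bcl2l11 (up to 0.103). Fas lost its call without either of these or either 12 h tunicamycin array (up to 0.199), and Ciart without any of these 4 or control 8 h replicate 2 (up to 0.256; 0.774 without the 12 h control).

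Of 15 oxidative stress response genes, 3 were higher and 2 lower (3 and 3 adjusted over the list alone; adjusted p = 0.926). The heme oxygenase gene Hmox1 rose by 1.40, the autophagy receptor gene Sqstm1 by 1.02 and the metallothionein gene Mt2 by 0.69, while the quinone reductase gene Nqo1 fell by 1.26. At 4 h Hmox1 did not lie above its control. Of 29 mitochondrial respiratory chain genes and regulators, 0 were higher and 4 lower (0 and 3 adjusted over the list alone; adjusted p = 0.132), with a median of -0.0339. The coactivator Ppargc1b fell by 1.71 (SE 0.255), Sdhd and Sdhc, subunits of complex II, by 0.62 and 0.36, and Atp5o, a subunit of ATP synthase, by 0.35. The mitochondrial list was called lower without the 12 h control (adjusted p = 0.00672) on the 4 h and 8 h arrays alone (0.00923), with the deposited scaling (0.0104), with median centring (0.00404) and when each array was divided by its mean (0.0221). Of 9 substrates of IRE1-dependent decay, 1 was higher and 2 lower (1 and 4 adjusted over the list alone; adjusted p = 0.0643), with a median of -0.295. In it Scara3 and Pmp22, a myelin protein gene, fell by 2.24 and 0.49, while Rpn1 rose. That list was called lower without the 8 h tunicamycin array (adjusted p = 0.0372), on the 12 h arrays alone (0.0442), with the deposited scaling (0.0313), without a filter (0.0188) and when each array was divided by its mean (0.0355). The calls of Sdhd (0.108), Nqo1 (0.0588), Sqstm1 (0.0516) and Mt2 (0.0751) were lost without the 8 h tunicamycin array, where Sdhd was at -0.396 and Pmp22 at -0.319; Nqo1 was at -0.83 without the 12 h control. Atp5o and Pmp22 lost theirs without it, the 12 h control or control 8 h replicate 2 (up to 0.123 and 0.15). Sdhc lost its call without any 1 of the 6 arrays at 8 h and 12 h (up to 0.223), and Hmox1 without any of them except control 8 h replicate 1 (up to 0.186).

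The remaining lists were not called. Of 17 cytosolic heat shock proteins, 1 was higher (Hspa4l, 0.75) and 2 were lower (Cryab, -0.61, and Hspa8, -0.25), with the same counts adjusted over the list alone (adjusted p = 0.723). Of 23 autophagy and lysosome genes, 2 were higher (Sqstm1, and the calcium channel gene Mcoln1, 0.53) and 3 lower, among them the cathepsin genes Ctsa (-0.42) and Ctsb (-0.39), again with the same counts adjusted over the list alone (adjusted p = 0.926). Of 21 glycolysis and hypoxia genes, 2 were higher (Adm, 0.57, and Pfkp, 0.53) and 0 lower (1 and 0 adjusted over the list alone; adjusted p = 0.728). That list was called lower without the 12 h control (adjusted p = 0.0403) and on the 4 h and 8 h arrays alone (0.0423). The calls of Hspa4l, Hspa8 and Pfkp were lost without any 1 of 6 arrays (adjusted p up to 0.178, 0.175 and 0.238), and Pfkp was at 0.274 without the 12 h control. These were the 8 h and 12 h arrays, with the 4 h tunicamycin array in place of control 8 h replicate 1 for Hspa4l. Ctsa lost its call without any 1 of 5 of them, all but tunicamycin 12 h replicate 1 (up to 0.158). Ctsb lost it without the 8 h tunicamycin array (0.0806), and Cryab, Mcoln1 and Adm without that array or the 12 h control (up to 0.0914, 0.0899 and 0.128). With the mean of all probe sets Ctsa was at -0.0489 (adjusted p = 0.807), Mcoln1 at 0.152 (0.518) and Hspa4l at 0.344 (0.411). Of 19 ribosomal protein genes 0 were called (adjusted p = 0.886); the smallest p were those of Rpl11 (-0.24, adjusted p = 0.0593) and Rpl37 (-0.45, adjusted p = 0.0913). The ribosomal median of 0.0114 had the opposite sign to the mean of -0.0273 and to the direction of the test. It was negative with the deposited scaling (-0.376), median centring (-0.12) and division by the array mean (-0.0422). For the oxidative stress list a median of -0.0675 stood against a mean of 0.068 and a test toward higher values, and for the autophagy list a median of -0.0271 and a test toward lower values against a mean of 0.0414. Markers of other cell types were scarce. Of the 5 tested macrophage markers 0 were called (adjusted p = 0.926), with Cd53 at -0.56 (adjusted p = 0.176) and Laptm5 at 0.49 (0.236). Of 12 endothelial markers 0 passed the filter, and of 14 skeletal muscle markers 2 did, Acta1 (0.19, adjusted p = 0.611) and Des (0.08, adjusted p = 0.822), which became -0.15 and -0.252 with the deposited scaling.

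**Figure D2:**
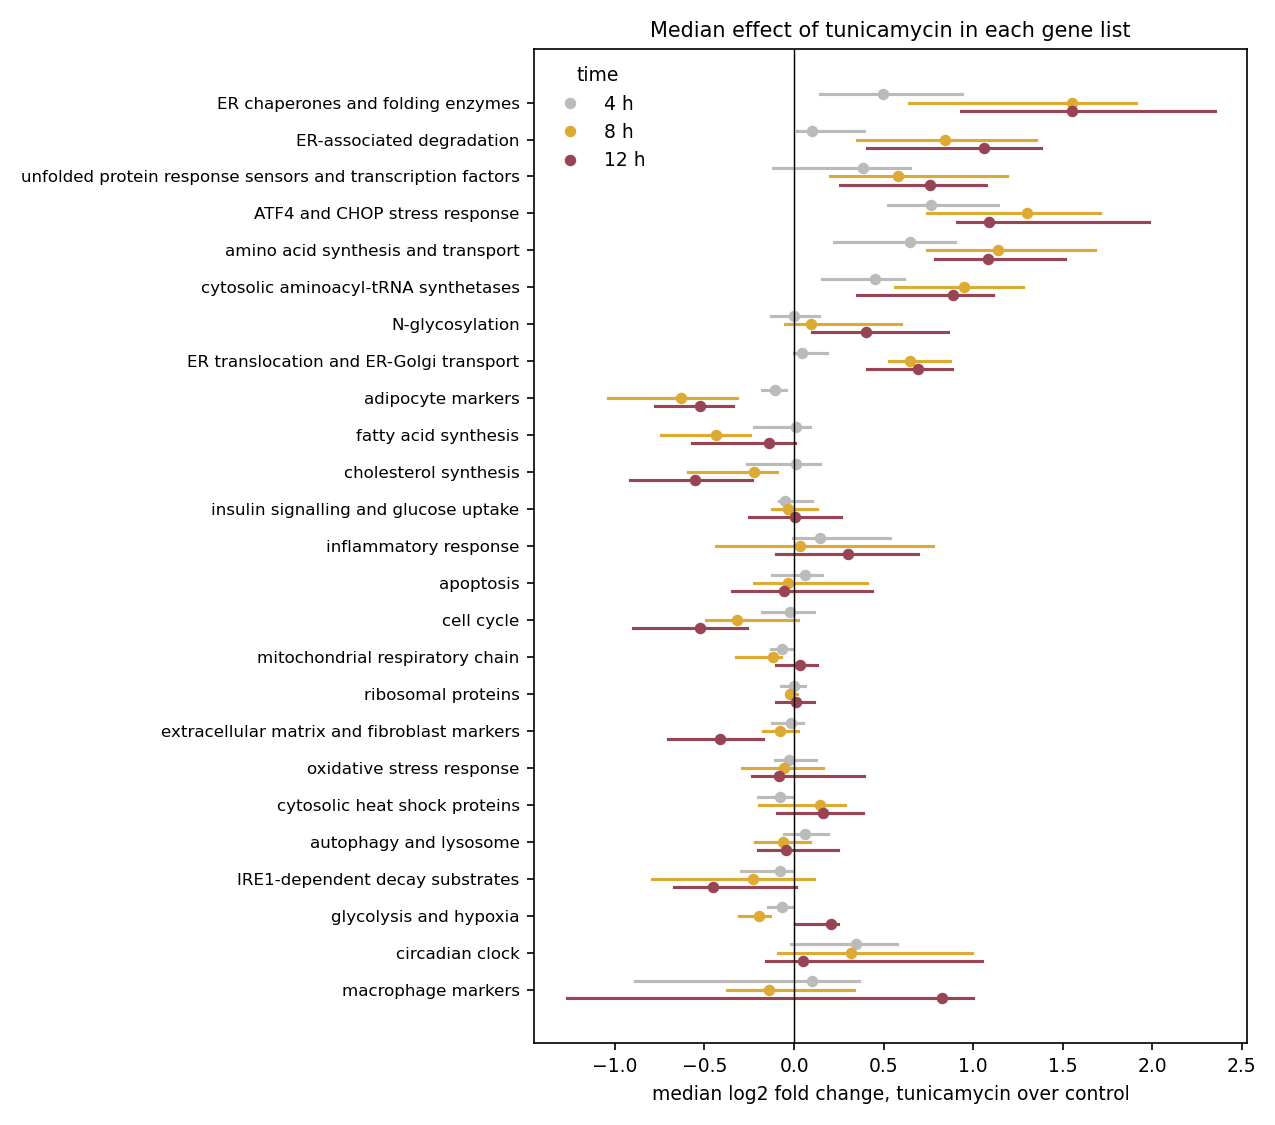
Median log2 fold change of tunicamycin over control in each tested gene list (horizontal axis), at 4 h, 8 h and 12 h, with bars for the 95% bootstrap interval over the list's genes. The ER chaperone median is 0.498 at 4 h and 1.55 at 8 h and 12 h, and the adipocyte marker median is -0.104, -0.629 and -0.524, all after quantile normalization.

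At 4 h, with 1 array in each group, 43 genes were called, 39 higher and 4 lower, and 1182 had an unadjusted p under 0.05. The number was 4 with the deposited scaling, 11 with the mean of all probe sets, 17 with every probe set tested and 21 on the 4 h and 8 h arrays alone. It was 71 with the highest pseudocount, 85 with the stricter filter, 133 without a filter and 215 with a replicate block. Without an intensity trend limma called 0 genes, and 1011 had an unadjusted p under 0.05. With the deposited scaling Herpud1 (2.99, adjusted p = 0.225), Ddit3 (2.71, 0.314), Chac1 (2.66, 0.789), Ppp1r15a (2.53, 0.938) and Creld2 (2.32, 0.938) were not called at 4 h. The genes raised the most included stress response genes. Herpud1 rose by 3.51 (SE 0.148, adjusted p = 3.1e-05), Ddit3 by 3.25 (SE 0.132, adjusted p = 3.1e-05), Chac1 by 3.22 (SE 0.189), Ppp1r15a by 3.11 (SE 0.224) and Creld2 by 2.92 (SE 0.142). Trib3 (2.80), Sdf2l1 (2.20), Atf4 (1.62) and Hspa5 (1.09) were also called. The 4 lower genes were Ercc2, a DNA repair helicase gene at or below 0 on the tunicamycin array (adjusted p = 0.0495), Ypel1 (-3.27, adjusted p = 0.00971), Fam43a (-1.31, adjusted p = 0.0344) and Cdc42ep2 (-1.13, adjusted p = 0.0457). Ypel1 had an intensity of only 7.63 on the tunicamycin array. It lost its call with the mean of all probe sets (-1.3), with every probe set tested, without a filter and without an intensity trend. The list tests called 7 lists higher and 0 lower. The medians were 0.763 for the ATF4 and CHOP stress response (6 of 21 genes higher, 14 adjusted over the list alone; adjusted p = 1.14e-21, and adjusted p = 0.244 with an estimated correlation), 0.498 for ER chaperones (6 of 28 higher, 15 adjusted over the list alone; 2.95e-12, and adjusted p = 0.244 with an estimated correlation) and 0.645 for amino acid synthesis and transport (3 of 22 higher, 12 adjusted over the list alone; 3.66e-11, and adjusted p = 0.254 with an estimated correlation). Medians were lower for aminoacyl-tRNA synthetases (0.451; adjusted p = 1.76e-05, and adjusted p = 0.468 with an estimated correlation), unfolded protein response sensors (0.387; adjusted p = 4.75e-05, and adjusted p = 0.254 with an estimated correlation), the inflammatory response (0.143; adjusted p = 0.00799, and adjusted p = 0.363 with an estimated correlation) and ER-associated degradation (0.1; adjusted p = 0.000409, and adjusted p = 0.363 with an estimated correlation). The adipocyte list had a median of -0.104 (adjusted p = 0.181). The 4 h tunicamycin array is the one with the beta-actin ratio of 2.81. Without control 8 h replicates 1 or 2, or tunicamycin 12 h replicates 1 or 2, which set the spread, 27, 27, 22 and 24 genes were called at 4 h, and Ercc2, Fam43a and Cdc42ep2 lost their calls each time (adjusted p up to 0.111, 0.101 and 0.126).

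At 8 h, 1 tunicamycin array was set against 2 controls, and 2005 genes were called, 1028 higher and 977 lower. The number was 39 with the deposited scaling, 1203 with median centring, 307 without a filter, 1122 with the mean of all probe sets and 717 without an intensity trend. Creld2 rose by 4.60 (SE 0.123, adjusted p = 1.44e-06), Sdf2l1 by 4.40 (SE 0.214), Bcat1 by 4.21 (SE 0.213), Tes by 4.03 (SE 0.596; intensities of 3.25 and 16.7 on the controls) and Herpud1 by 3.84 (SE 0.128). Among the lowest values were those of Adcyap1r1, a neuropeptide receptor gene that went from 52.1 and 57.4 on the controls to 0.595 on the tunicamycin array, below the pseudocount (adjusted p = 0.00404), of Med18 and Smim27, both at or below 0 on that array (adjusted p = 0.00645 and 0.00138), and of Kctd12b (-3.40, SE 0.274) and C1qtnf6 (-3.39, SE 0.601; an intensity of 4.66 on the tunicamycin array). Irs1 fell by 2.21 (adjusted p = 5.38e-05), Cebpa by 2.0 (adjusted p = 0.000718) and Pparg by 1.70 (adjusted p = 0.000115). List tests called 8 lists higher and 3 lower. ER chaperones had 22 of 28 genes higher (24 adjusted over the list alone) and a median of 1.55 (adjusted p = 2.52e-21, and adjusted p = 0.164 with an estimated correlation). Adipocyte markers had 12 of 24 lower (13 adjusted over the list alone) and a median of -0.629 (adjusted p = 4.38e-08, and adjusted p = 0.164 with an estimated correlation). Fatty acid synthesis had a median of -0.434 (adjusted p = 6.71e-05, and adjusted p = 0.328 with an estimated correlation), and the respiratory chain one of -0.119 (adjusted p = 0.00612, and adjusted p = 0.531 with an estimated correlation). Leaving out control 8 h replicate 1 or 2 gave 943 and 947 called genes.

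At 12 h, 2 tunicamycin arrays were set against 1 control, and 2295 genes were called, 1100 higher and 1195 lower. The number was 74 with the deposited scaling, 637 without a filter, 1309 with the mean of all probe sets and 1108 without an intensity trend. Sdf2l1 rose by 5.39 (SE 0.214, adjusted p = 7.75e-06), Mreg by 5.03 (SE 0.34; an intensity of 3.75 on the control array), Creld2 by 4.76 (SE 0.123), Il6 by 3.71 (SE 0.347) and Car6, a secreted carbonic anhydrase gene with an intensity of 7.57 on the control array, by 3.68 (SE 0.598). Among the lowest, Rgs16, a regulator of G protein signalling, was at or below 0 on both tunicamycin arrays (adjusted p = 0.00132), Crip1 on 1 of them (adjusted p = 0.0116) and Gtse1, a mitotic gene, on 1 of them, with 0.559 on the other (adjusted p = 0.00423). Ankef1 fell by 3.97 (SE 0.651; intensities of 2.01 and 15.7) and Cygb, which encodes cytoglobin, went from 55.9 on the control to 1.5 and 1.29, below the pseudocount (adjusted p = 0.00242). With the mean of all probe sets Ankef1 was at -1.02 at 12 h and was not called. List tests called 8 lists higher and 6 lower. ER chaperones had 26 of 28 genes higher, also when adjusted over the list alone, and a median of 1.55 (adjusted p = 6.09e-24, and adjusted p = 0.159 with an estimated correlation). N-glycosylation had 15 of 38 higher and 0 lower (16 and 2 adjusted over the list alone) and a median of 0.402 (adjusted p = 7.92e-06, and adjusted p = 0.159 with an estimated correlation). Matrix and fibroblast markers had 15 of 30 lower (17 adjusted over the list alone) and a median of -0.412 (adjusted p = 4.51e-06, and adjusted p = 0.432 with an estimated correlation), and cell cycle genes 11 of 26 lower (14 adjusted over the list alone) and a median of -0.527 (adjusted p = 2.38e-05, and adjusted p = 0.456 with an estimated correlation). Adipocyte markers had a median of -0.524 (adjusted p = 4.51e-06, and adjusted p = 0.191 with an estimated correlation), cholesterol synthesis -0.552 (adjusted p = 0.0105, and adjusted p = 0.234 with an estimated correlation), fatty acid synthesis -0.142 (adjusted p = 0.0284, and adjusted p = 0.456 with an estimated correlation) and IRE1 decay substrates -0.451 (adjusted p = 0.0348, and adjusted p = 0.359 with an estimated correlation). The 12 h arrays are those with the lower BioC to BioB ratio, in both groups.

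**Figure D3:**
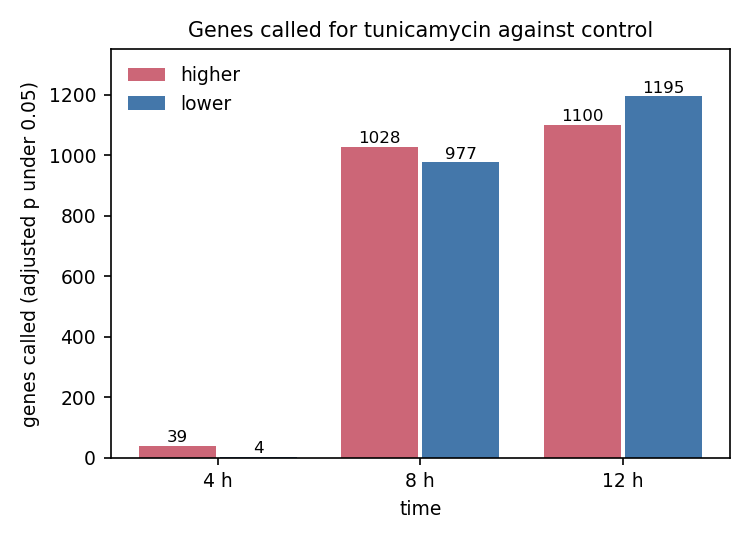
Bars give the number of genes called higher or lower with tunicamycin (adjusted p under 0.05, quantile-normalized values) at each time in hours. The bars stand at 39 and 4 genes at 4 h, 1028 and 977 at 8 h, and 1100 and 1195 at 12 h.

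Whether the effect of tunicamycin differed between times was tested on its own. The F test called 188 genes, 85 with an effect that was higher at 12 h than at 4 h and 103 with one that was lower, and 1874 had an unadjusted p under 0.05. The call depends on the setting. With the deposited scaling, the mean of all probe sets, every probe set tested or no intensity trend limma called 0, with 87, 1470, 3240 and 1484 at an unadjusted p under 0.05. Median centring gave 68, leaving out probe sets shared between transcripts 125, the stricter filter 316 and a replicate block 724. The effect on Sdf2l1 was 2.20, 4.40 and 5.39 at 4 h, 8 h and 12 h (F test, adjusted p = 0.0205), and that on Mreg, whose 12 h control was at 3.75, 0.27, 3.23 and 5.03 (adjusted p = 0.0259). The rise from 4 h to 12 h was also among the 5 largest for 1810010H24Rik (3.68) and Edn3, an endothelin gene (2.91). Lower effects at 12 h than at 4 h were those on the interferon-inducible genes Ifit3 (-3.47, adjusted p = 0.0235) and Ifit1 (-2.99, adjusted p = 0.0259) and on Pnpla3 (-3.36, adjusted p = 0.0446). Prelid3a, called with a rise, was at or below 0 on the 12 h control, and Wfikkn1 and Myo18a, called with a fall, on the 4 h control, so the fitted differences of these 3 rest on the pseudocount and are not folds. Among adipocyte regulators, the effect on Pparg was 0.22 at 4 h, -1.70 at 8 h and -1.10 at 12 h (F test, adjusted p = 0.0205), and that on Cebpa -0.18, -2.0 and -1.98 (adjusted p = 0.0446). The effect on Ddit3 was 3.25, 3.24 and 3.09, and that on Hspa5 1.09, 1.53 and 1.51. Leaving out control 8 h replicate 1 or 2, or tunicamycin 12 h replicate 1 or 2, lowered the number of genes to 7, 12, 57 and 104. Prelid3a, 1810010H24Rik, Edn3 and Wfikkn1 lost their calls in each of these runs (adjusted p up to 0.14, 0.0844, 0.104 and 0.169), Myo18a and Pnpla3 without either 8 h control (up to 0.157 and 0.118), Mreg without either 8 h control or tunicamycin 12 h replicate 1 (up to 0.0544), and Ifit1 without tunicamycin 12 h replicate 1 (0.0553).

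The effects at the separate times correlated across genes, which are not independent replicates. Pearson's r was 0.422 between 4 h and 8 h, 0.311 between 4 h and 12 h and 0.647 between 8 h and 12 h, and Spearman's rho 0.416, 0.299 and 0.599. Without a filter Pearson's r was 0.136, 0.125 and 0.34, and with every probe set tested 0.267, 0.156 and 0.44. The 3 effects use different arrays, so no control is shared. Their tests do share the same estimate of spread for each gene, so the calls at the 3 times are not independent. The numbers expected for independent lists are thus only a rough reference. All 39 genes higher at 4 h were also called higher at 8 h (3.67 expected for independent lists) and 37 at 12 h (3.93 expected). Of the 4 lower at 4 h, 2 were lower at 8 h (0.358 expected) and 2 at 12 h (0.438 expected). Between 8 h and 12 h, 640 higher genes (104 expected) and 586 lower genes (107 expected) were shared. Over the 2295 genes called at 12 h, the median effect in the direction seen at 12 h was 0.201 at 4 h, 0.659 at 8 h and 0.921 at 12 h.

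Changes with time common to both arms were few. Between 4 h and 12 h, 2 genes were higher and 6 lower, and 1908 had an unadjusted p under 0.05. Emp3, a membrane protein gene, rose by 1.37 (SE 0.165, adjusted p = 0.0421) and Rtl8c by 1.19 (SE 0.161, adjusted p = 0.0475). Apol6 (adjusted p = 0.0421) went from 26.5 to 69 on the 4 h and 8 h arrays to 0.144 to 1.7 on the 12 h arrays, which lies below the pseudocount, so no size is given. Syn2 fell by 1.5 (SE 0.205), the mitophagy receptor gene Bnip3 by 1.14 (SE 0.142), the clock repressor gene Nr1d2 by 1.10 (SE 0.14) and Apmap, an adipocyte membrane protein gene, by 1.06 (SE 0.15). Between 4 h and 8 h limma called 0 genes, and 444 had an unadjusted p under 0.05. This comparison cannot be separated from the BioC to BioB difference between the 12 h arrays and the others. With the deposited scaling 128 genes were called, and with median centring 1. Without the 4 h control 1099 genes were called and without the 12 h control 543. Without the 4 h tunicamycin array, either 8 h control or either 12 h tunicamycin array the number was 0, and the 7 genes named here lost their calls (adjusted p up to 0.358 for Emp3, 0.478 for Rtl8c, 0.442 for Apol6, Syn2 and Bnip3, 0.358 for Nr1d2 and 0.478 for Apmap). Rtl8c and Nr1d2 also lost theirs without the 8 h tunicamycin array.

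The authors' deposited table of ratios listed 1868 probe sets at 4 h with a p-value under 0.01 (1015 above 0 and 853 below). By chance 451 of 45101 would be expected if these p-values measured the spread between cultures, which is not known. At 8 h the authors' deposited table listed 5207 (2792 and 2415) and at 12 h 5262 (2306 and 2956). Across genes the log ratios in the authors' deposited table correlated with the effects computed here at r = 0.816, 0.926 and 0.915 at the 3 times. The direction of the ratios was read from this correlation, and they may rest on the same arrays. Neither the correlation nor the shared signs are therefore an independent check. All 43 genes called here at 4 h, 2001 of 2005 at 8 h and 2293 of 2295 at 12 h had the same sign in the authors' deposited table, and 41, 1845 and 1996 of them also had a p-value under 0.01 in the authors' deposited table. Among the genes named at single times, it was above 0.01 in the authors' deposited table for Ercc2 (0.784) and Ypel1 (0.442) at 4 h, for Med18 (0.738), Smim27 (0.319) and C1qtnf6 (0.0111) at 8 h and for Gtse1 (0.401) at 12 h. In the authors' deposited table Prelid3a, Wfikkn1 and Myo18a had p-values of 0.333 or above at every time. For Creld2 the authors' deposited table gave ratios of 6.18, 21.7 and 26.5 at 4 h, 8 h and 12 h, and for Herpud1 12.1, 15.5 and 12.4.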

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

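The tests of the adipocyte markers below were chosen only after their result was seen; the other tests in this part were set out before their results were seen.

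Genes were singled out where limma's F test found that the effect of tunicamycin differed between the times, which held for 188 genes. The same test in limma called 0 genes with the deposited scaling, where 87 had an unadjusted p under 0.05. The effect at 12 h exceeded that at 4 h by 4.76 for Mreg (its 12 h control at 3.75), 3.68 for 1810010H24Rik, 3.18 for Sdf2l1 and 2.91 for Edn3 on the log2 scale. The difference was -3.47 for Ifit3, -3.36 for Pnpla3 and -2.99 for Ifit1. Prelid3a at 12 h, and Wfikkn1 and Myo18a at 4 h, had a control at or below 0; their fitted values of 4.09, -4.21 and -4.17 rest on the pseudocount and are not folds. The F test called only 7 and 12 genes without control 8 h replicates 1 and 2, and 57 and 104 without tunicamycin 12 h replicates 1 and 2. Without at least 1 of these arrays, 8 of the 10 named genes lost their calls; Sdf2l1 and Ifit3 (adjusted p up to 0.0496 each) did not.

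Gene lists were singled out where the same difference, 12 h minus 4 h, passed the camera test. The median difference was 1.03 for ER chaperones (adjusted p = 1.33e-23, and adjusted p = 0.232 with an estimated correlation), 0.668 for ER-associated degradation (4.63e-12, and adjusted p = 0.232), 0.577 for amino acid synthesis and transport (7.25e-08, and adjusted p = 0.288), 0.574 for ER translocation and ER-Golgi transport (6.93e-16, and adjusted p = 0.288), 0.536 for N-glycosylation (4.49e-08, and adjusted p = 0.232), 0.39 for aminoacyl-tRNA synthetases (0.000128, and adjusted p = 0.454) and 0.299 for glycolysis and hypoxia (0.00356, and adjusted p = 0.47). It was -0.479 for the cell cycle (8.2e-05, and adjusted p = 0.536), -0.454 for adipocyte markers (5.67e-05, and adjusted p = 0.288), -0.425 for cholesterol synthesis (0.0416, and adjusted p = 0.427) and -0.369 for matrix and fibroblast markers (8.19e-06, and adjusted p = 0.47). The second value for each list is that with an estimated correlation. The lists of the ATF4 and CHOP stress response (adjusted p = 0.0664) and of unfolded protein response sensors (0.157) were not among them.

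The small number of genes at 4 h was weighed against the array numbers and against noise. With 1 control and 1 tunicamycin array at 8 h, the layout of the 4 h comparison, 1420 or 1367 genes were called, depending on which control was used, against 43 at 4 h, which argues against the number of arrays as the cause. The spread used for these counts still came from the full fit with both 8 h controls. With 1 of them left out of the fit altogether the counts at 8 h were lower, as given above, and still far above those at 4 h. Over the genes called at 12 h, the median effect at 4 h was 0.305 of that at 8 h. The 95% bootstrap interval over these genes was 0.281 to 0.331. Equal effects hidden by noise that differs from gene to gene are thus argued against too. With 1 tunicamycin array at 4 h and 1 at 8 h, that interval does not measure the spread between arrays. The 4 h tunicamycin array nevertheless had a beta-actin 3' to 5' ratio of 2.81 and a pyruvate carboxylase ratio of 43.5, both outside the range of the controls, and no other array of that group was analysed here. A response that builds up between 4 h and 8 h may account for the pattern; how far the RNA of that 1 array shrank its effects was not tested.

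The fall of adipocyte markers was weighed against a smaller share of fat cells and against RNA quality. A larger share of undifferentiated fibroblasts would by itself raise the markers of matrix and fibroblasts. At 12 h their median was -0.412 (95% interval -0.701 to -0.173), with 1 control array, so no rise was seen. A fall of these genes within cells could mask a rise, so this cannot decide. Col6a1, Pdgfrb and Sparc also stand in the list of IRE1-dependent decay substrates, whose median at 12 h was -0.451. At 8 h, where the adipocyte median was -0.629, the matrix and fibroblast median was -0.0805 (95% interval -0.173 to 0.0247). Both intervals are over the genes of the matrix and fibroblast list and do not measure the spread between arrays. A smaller share of fat cells stays open at both times. RNA quality stays open, because the beta-actin ratio of the 8 h and 12 h tunicamycin arrays, up to 1.71, lay above the controls of their own times (1.51 to 1.57), while those of GAPDH and pyruvate carboxylase lay above at 8 h (0.971 and 19.8 against up to 0.873 and 15.3) and below at 12 h (0.902 and 12.6 or less, against 0.909 and 13.9). A lower level of adipocyte transcripts in each fat cell may account for the fall as well, as a hypothesis found and tested on the same arrays.

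The number of genes called over all times was set against the other ways of splitting the 8 arrays into 4 and 4. Of 35 splits, only 1, the real one, gave 2264 genes, the smallest share that 35 splits can give, and the highest of the others gave 0. The splits were not confined to exchanges within a time. Where tunicamycin has an effect, the other splits leave it in the residuals, which lowers their counts. For both reasons the splits cannot exclude chance for the gene count. For the number of called lists chance cannot be excluded in this way either: 7 of the 35 splits gave at least the 13 of the real one, and the highest of the others 14. Nor do the splits show that chance gives 13, because the 6 others each exchange only 1 control and 1 tunicamycin array and so largely follow the treatment; the 18 that exchange 2 of each gave at most 11. With an estimated correlation camera called 0 lists.

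Probe sets with no gene symbol stood outside every gene test. Of 3568 above the filter, 153 (4.29%) were called over all times when each probe set was tested, 74 higher and 79 lower, against 11.8% of those with 1 symbol.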

How the results depend on the processing

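Division by the array mean, the highest pseudocount, the runs without both 4 h arrays and the runs within the 4 h and 8 h arrays or the 12 h arrays alone were chosen after seeing the data. The number of arrays and the low signal limit the results: 19.2% to 20.9% of the values of each array lay at or below 0, and few arrays set the spread. Of 3681 values of single named genes under all settings together, 3057 had the same direction and the same side of the threshold, 602 fell below it, 10 rose past it and 12 changed sign. The losses were uneven: 98 of 156 values fell below the threshold without a filter, 50 of 156 with the deposited scaling, 47 of 156 without the intensity trend, 38 of 152 with the mean of all probe sets, 26 of 156 with every probe set tested, 12 of 156 with the replicate block, 11 of 156 with median centring, and 8 or fewer in each other setting that kept all arrays. With an array left out they numbered 60 of 136 without the 8 h tunicamycin array, 36 of 136 without the 12 h control, 27 to 34 of 156 without either 8 h control or either 12 h tunicamycin array, and 8 and 0 of 137 without the 4 h tunicamycin array and the 4 h control. The 12 that changed sign were all uncalled: Acta1 (-0.15), Des (-0.252) and Insr (-0.204) with the deposited scaling, Des with the mean of all probe sets (-0.445), without the 12 h control (-0.245) and on the 4 h and 8 h arrays (-0.245), Adipoq without control 8 h replicate 1 (0.00246), and Slc2a1 without the 4 h control, the 4 h tunicamycin array or both (0.0258), when each array was divided by its mean (0.0249) and on the 12 h arrays (0.0376). With each array left out in turn, Des ran from -0.245 to 0.299, Slc2a1 from -0.0586 to 0.0258 and Adipoq from -0.0609 to 0.00246.

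The lists that follow name the counts that moved by over 1.5 times and the correlations that moved by more than their spread, along with some that moved less; the cause was not tested unless given. With the deposited scaling 143 genes were higher over all times, 4 were called at 4 h, 39 at 8 h, 74 at 12 h, 0 by the F test and 128 between 12 h and 4 h. The 850 genes called over all times with that scaling shared 723 with the 2264. Median centring gave 794 higher genes over all times (895 lower), 1203 at 8 h, 68 by the F test and 1 between 12 h and 4 h. Division by the array mean gave 1316 higher and 944 lower. A fold of at least 2 left 275 higher and 213 lower genes by construction, and an estimated correlation left 0 lists.

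The lower pseudocount of 0.739 gave r = 0.292 between the effects at 4 h and 12 h and 0 genes between 12 h and 4 h. A pseudocount 4 times as large gave r = 0.46, 0.347 and 0.691 between 4 h and 8 h, 4 h and 12 h, and 8 h and 12 h, and one 16 times as large r = 0.527, 0.409 and 0.744 and 71 genes at 4 h. Without the filter 400 genes were higher and 178 lower over all times, 133 were called at 4 h, 307 at 8 h, 637 at 12 h and 2 between 12 h and 4 h, and r was 0.136, 0.125 and 0.34. With the filter at the 60th percentile 85 genes were called at 4 h and 316 by the F test, and r was 0.584, 0.465 and 0.778. The mean of all probe sets of a gene gave 702 higher genes, 11 at 4 h, 1122 at 8 h, 1309 at 12 h, 0 by the F test, 1 between 12 h and 4 h, and r = 0.336, 0.246 and 0.59. Testing every probe set gave 17 at 4 h, 0 by the F test and r = 0.267, 0.156 and 0.44. Leaving out probe sets shared between transcripts gave 125 by the F test and r = 0.294 between 4 h and 12 h. Without the intensity trend 600 genes were lower over all times, 0 were called at 4 h, 717 at 8 h, 1108 at 12 h, 0 by the F test and 1 between 12 h and 4 h. The 4 h and 8 h arrays alone gave 347 higher and 140 lower genes over all times and 21 at 4 h. With robust moderation, without both 4 h arrays and on the 12 h arrays alone, each count that could be had stayed within 1.5 times.

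Taking the replicate number as a paired term (replicate block) gave 976 higher and 861 lower genes over all times, 215 at 4 h, 724 by the F test, 0 between 12 h and 4 h, and r = 0.384 between 4 h and 8 h and 0.527 between 8 h and 12 h. The 1837 genes called over all times with the block shared 1812 with the 2264. Replicates 1 and 2 of the 8 h controls and of the 12 h tunicamycin arrays did not deviate together (r = 0.0323), which gave no sign of a pairing. The check sets arrays of different times and treatments against each other, so it cannot exclude one.

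Leaving out each array in turn gave 270 to 1427 higher genes and 104 to 1523 lower genes over all times, both lowest without the 8 h tunicamycin array, where 369 of 374 called genes were among the 2264. It gave 22 to 49 genes at 4 h, 943 to 2303 at 8 h, 1724 to 2319 at 12 h, 7 to 104 by the F test, 0 to 1099 between 12 h and 4 h, and 11 to 15 lists. The correlation ran from 0.376 to 0.438 between 4 h and 8 h, from 0.284 to 0.311 between 4 h and 12 h and from 0.599 to 0.647 between 8 h and 12 h. An effect at a time whose only array of a group was left out, and the F test then, gave no value. Nor did the 12 h effects and the time effect on the 4 h and 8 h arrays alone, or any other time on the 12 h arrays alone.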

Other observations

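The tests of interferon-inducible genes and of GPI anchor genes were set out after Ifit1, Ifit3 and Piga had been seen among the changed genes. They were set out before the other members were looked at, apart from 2 interferon-inducible genes that stood in lists tested earlier. The genes named in this part were chosen after their values were seen.

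Interferon-inducible genes were lower with tunicamycin at the later times. A list of 44 such genes was written from general knowledge, without Ifit1 and Ifit3; 38 passed the filter, and 2 stand in another list as well. At 12 h, 29 of the 38 were lower and 0 higher, with a median log2 fold change of -1.10 (camera p = 3.44e-16, and p = 0.113 with an estimated correlation). Mx1, an antiviral GTPase gene, was at -3.21 (adjusted p = 0.00401), Oas1a, which encodes a sensor of double-stranded RNA, at -2.54 (adjusted p = 0.00137) and Zbp1 at -2.18 (adjusted p = 0.00719). The guanylate-binding protein gene Gbp3 was at -1.94 (adjusted p = 0.000493), Eif2ak2, which encodes the kinase PKR, at -1.48 (adjusted p = 0.00112) and Psmb8, an immunoproteasome subunit gene, at -1.35 (adjusted p = 0.00876), while Irf1 was at 0.15 (adjusted p = 0.548). At 8 h, 12 members were lower and 0 higher, with a median of -0.539 (p = 1.31e-06, and p = 0.249 with an estimated correlation). At 4 h none of the members was called. The list's median there was 0.0606 (p = 0.665, and p = 0.899 with an estimated correlation).

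The fall at 12 h was weighed against single arrays. A high value on the only 12 h control could give it, but that array's list median lay only 0.256 (95% interval 0.0959 to 0.348) above the mean of the other 3 controls, against a fall of 1.10. A low value on 1 tunicamycin array is argued against as well, since each of the 2 alone gave a fall, with medians of -0.998 (95% interval -1.29 to -0.81) and -1.18 (-1.29 to -0.941). All of these intervals are over the list's genes and do not measure the spread between arrays. Control and tunicamycin arrays at 12 h share the lower BioC to BioB ratio, so that split does not separate them. A fall of the interferon response with tunicamycin may account for the pattern. The camera p of 3.44e-16 goes with it but is not independent support. The list was written after Ifit1 and Ifit3 were seen on these same arrays, and 2 of its members had stood in lists tested earlier. The value with an estimated correlation (0.113) leaves it open, and RNA quality was not tested for these genes.

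Piga, which encodes the catalytic subunit of the first enzyme of GPI anchor synthesis, had a log2 fold change of 2.67 over all times (SE 0.213, adjusted p = 0.000137). The hypothesis that the GPI anchor pathway rises with tunicamycin was tested on 24 other genes of the pathway. Of 19 above the filter, 0 were higher and 3 lower, with a median of -0.196 (camera p = 0.0315 in the lower direction, and p = 0.147 with an estimated correlation), so the others did not rise with Piga.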
